A study of Mus musculus with 8 samples.

How the data were processed

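Gene expression was measured by RNA sequencing in 8 samples of the mouse alveolar macrophage line MH-S, in 3 groups taken from the sample titles: control (n = 3), LPS (n = 2) and LPS+RCMNs (n = 3). Per the labels' protocols, RNA was extracted with TRIzol, messenger RNA was enriched with oligo(dT) beads and libraries were made with a BGI kit. The authors deposited a table of 17518 genes with an expected (estimated) count and an FPKM value per library. Per the file headers the columns are read counts and FPKM. Of the deposited counts above 0, 77.8% were more than 0.001 from a whole number, so they are estimated counts. The genome build is mm10 per the submitters' processing notes, and reads were checked with FastQC per the series' design text. The aligner, the counting tool and the annotation are not given in the sources used here. The FPKM values, per kb of gene and M reads, are the authors' own. Columns were matched to samples by the library code in each sample's description, and 4 per-sample columns with a code that no sample carries were not used.

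Counts were rounded to whole numbers. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3, no robust prior) with all 8 samples in 3 groups, so that the LPS group with 2 libraries shared the estimate of spread. Calls were made at a Benjamini-Hochberg adjusted p below 0.05, with no minimum fold. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 14.5%, with 4.15 prior and 5 residual degrees of freedom. TMM factors were 0.779 and 0.803 for the LPS libraries and 1.05 to 1.13 for the others. CPM values are rounded counts per M (mega) of scaled library size, and floors use 3 counts. Gene length is the length implied by the deposited counts and FPKM. Gene IDs were matched to a GRCm38.p6 gene table (17468 of 17518, 99.7%), which places Il1b (gene ID 16176) on chromosome 2 at 129364569 to 129371164, Il6 (16193) on chromosome 5 at 30013114 to 30019975, Lcn2 (16819) on chromosome 2 at 32384637 to 32387739, Hspa1b (15511) on chromosome 17 at 34956429 to 34959238 and Tnf (21926) on chromosome 17 at 35199367 to 35202007.

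Before the data were examined, 29 gene lists, the design, the alternatives and the rule for named genes were fixed. The rule took, per comparison, the 6 largest rises and 6 largest falls among called genes with a mean FPKM of at least 5 and no overlap between the groups, the 3 called members of smallest p in the direction of each called list, and 12 fixed genes. Il10, one of the 12, was not tested: its highest level was 0.242 CPM. Lists were tested with camera on log2 CPM with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 25 lists with at least 5 tested members within each comparison, and again with a correlation estimated per list. Of the lists not tested, the mitochondrially encoded genes were not among the listed genes, and neutrophil, lymphocyte and epithelial markers had 4, 2 and 1 tested members and a highest level in any library of 33.4, 12.2 and 0.650 CPM. Genes are named in places by a later choice, which is then said.

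The procedure was tested on simulated data with 11911 genes, of which 67, 67 and 66 per comparison were changed 1.5-, 2- and 4-fold. It called 29.9%, 71.6% and 98.5% of genes changed 1.5-, 2- and 4-fold for LPS versus control, 29.9%, 70.1% and 100% for LPS+RCMNs versus LPS, and 46.3%, 91.0% and 100% for LPS+RCMNs versus control, with 0.0683%, 0.0769% and 0.0598% of unchanged genes called.

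Alternatives fixed in advance were a fit of only the groups compared, the replicate number as a block, each library left out in turn, a fold minimum (absolute log2 fold change of 1), no filter, a stricter filter (FPKM of at least 5 in at least 2 libraries), median-ratio size factors, DESeq2 1.42.0, limma on log2(FPKM + 1) and a robust prior. Pseudocounts other than 1 had been planned only for a table without counts and were not run. After the data were seen, fits were added with a smooth trend of each library on gene length removed (loess, span 0.4), with a trend on GC content also removed (97.3% of tested genes had a GC content), with a surface on length and mean expression level removed, and without control replicate 1 and LPS+RCMNs replicate 2, and camera was also run on log2(FPKM + 1).

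Further tests, also chosen after the data were seen, used a fit with a trend on GC content alone removed, 1000 draws of genes outside all lists from the 20 nearest neighbours of each list member in length and mean expression level, and permutation over 10000 random lists of genes of like mean level for the cell type markers and for an erythroid list. The overlap of calls was simulated with 30 draws of unchanged groups that share libraries as the real comparisons do.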

Results

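The study concerned nanoparticles that respond to reactive oxygen species, made for imaging and treating acute lung injury through alveolar macrophages, the resident phagocytes of the airspaces. Polyadenylated RNA was sequenced from MH-S cells, a mouse alveolar macrophage line. The 8 libraries formed 3 groups: control cells given phosphate-buffered saline (n = 3), cells given lipopolysaccharide (LPS, a bacterial cell wall component that activates macrophages; n = 2), and cells given LPS together with nanoparticles named RCMNs (n = 3). The combined treatment used 100 ng/mL LPS and 1 µg/mL RCMNs, and no separate dose was stated for LPS alone. Total counts ran from 18.6 to 21.2 M (mega) per library, and 13780 to 15266 of the 17518 listed genes had a count. Of these, 11911 were tested. At this depth a gene with no count in a library could have a level of up to 0.130 to 0.182 CPM (counts per M of the scaled library size), depending on the library, counting error only. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

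The first principal component held 67.4% of the variance and separated both LPS libraries from the other 6. In the LPS libraries, levels relative to control depended on gene length: the median log2 level of the shortest 10% of genes was 1.22 and 1.24 above the control mean, and that of the longest 10% was -1.03 and -0.94. Across genes, the rank correlation of the LPS versus control fold change with gene length was -0.58, against -0.09 for LPS+RCMNs versus control, although the LPS+RCMNs cells had also received LPS. Transcripts of the globins, the oxygen carriers of red blood cells, summed to 4959 ± 892 CPM (SD, n = 2) in LPS, 13.7 ± 11.4 CPM (SD, n = 3) in control and 21.3 ± 18.0 CPM (SD, n = 3) in LPS+RCMNs. The control and LPS+RCMNs means mix 2 levels: 0.477 CPM in control replicate 1 and 0.608 CPM in LPS+RCMNs replicate 2, against 20.1 to 33.5 CPM in the other 4 libraries. The same 2 libraries, control replicate 1 and LPS+RCMNs replicate 2, stood apart from their groups. Against the other replicates the chi-square per degree of freedom was 46.9 and 49.9 for the former and 37.5 and 45.1 for the latter. It was 1.96 between control replicates 2 and 3 and 2.91 between LPS+RCMNs replicates 1 and 3. Between the 2 LPS libraries it was 13.3, so these also differed more than the close pairs.

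**Figure D1:**
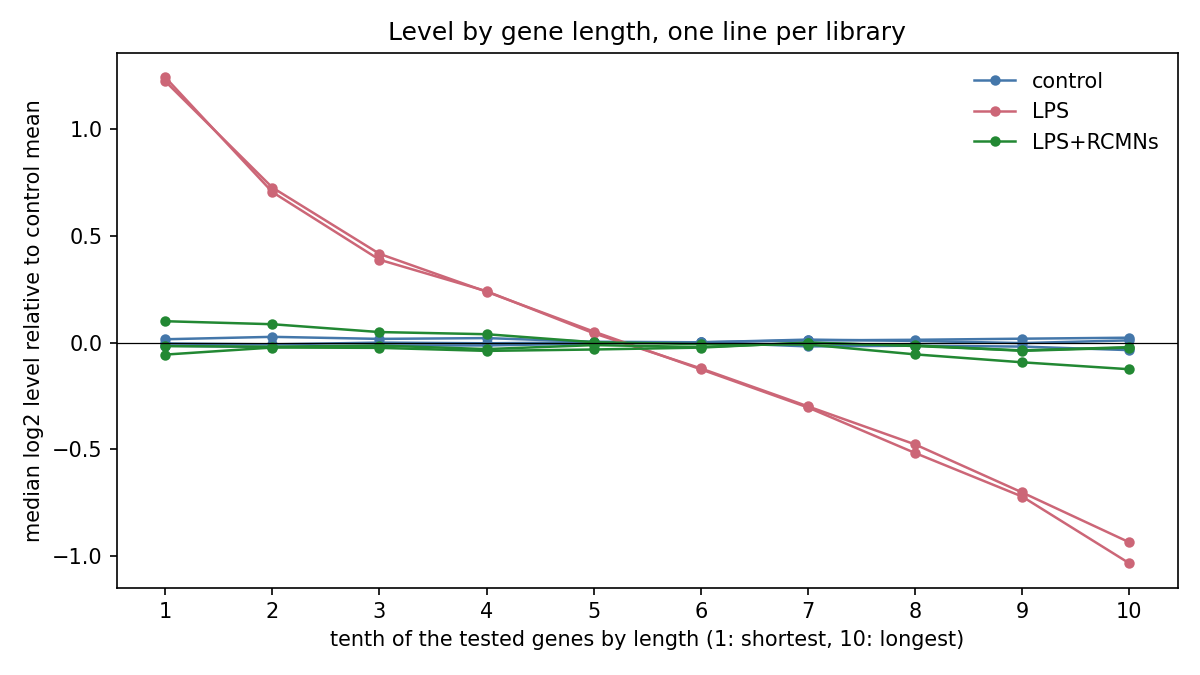
Median log2 level relative to the control mean in 10 bins of the tested genes by length, from the shortest (1) to the longest (10), with a line per library coloured by group. Both LPS lines fall from about 1.2 to about -1.0, and the lines of the other libraries lie between -0.13 and 0.10.

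The LPS versus control comparison asks what LPS changed in these macrophages. Genes of the inflammatory response rose. Il1b, which encodes the fever-inducing cytokine interleukin-1 beta, went from 0.169 ± 0.109 CPM (SD, n = 3) in control to 351.7 ± 3.86 CPM (SD, n = 2) in LPS, a log2 fold change of 10.99 ± 0.22 (SE). Il6, encoding the cytokine interleukin-6, rose by 8.18 ± 0.23, Csf3, a growth factor for neutrophils, by 9.77 ± 0.43, and Lcn2, an iron-binding antibacterial protein, by 9.09 ± 0.20. Of the 48 tested inflammatory genes, 41 rose, 2 fell and 5 were not called, with a median log2 fold change of 2.64 (camera adjusted p = 7.1e-12). With an estimated correlation the adjusted p of that list was 0.145. Cxcl10, a chemokine induced by interferon, rose by 6.05 ± 0.17, and 26 of 42 interferon response genes rose while 2 fell (adjusted p = 4.41e-04; adjusted p = 0.758 with an estimated correlation). The control levels of Csf3, Nos2, Lcn2 and Il1b rest on 6, 6, 10 and 11 counts over 3 libraries, at or near the floor, so the size of these folds is uncertain: for Csf3 it ran from 5.58 (limma) to 11.57 (without control replicate 3). Nos2, the inducible nitric oxide synthase, rose by 4.82 ± 0.58 but stayed at 2.73 ± 0.170 CPM (SD, n = 2). Tnf, a central macrophage cytokine, rose by 1.21 ± 0.39 (adjusted p = 0.023), a call that was lost without LPS replicate 2 and after correction for gene length.

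Heat shock genes, Nrf2 targets and scavengers of reactive oxygen species rose as well. Hspa1a and Hspa1b, neighbouring and nearly identical genes for the inducible chaperone HSP70 on chromosome 17, went from 0.254 ± 0.220 and 0.193 ± 0.177 CPM (SD, n = 3) to 756.8 ± 254 and 1008 ± 38.5 CPM (SD, n = 2), log2 fold changes of 11.49 ± 0.56 and 12.28 ± 0.58 on 17 and 13 control counts. How reads shared by such copies were divided is uncertain, here and for the globins. In all, 16 of 18 heat shock genes rose and none fell (median 1.14, adjusted p = 2.71e-06; adjusted p = 0.145 with an estimated correlation). Of 28 targets of Nrf2, the transcription factor of the antioxidant response, 20 rose and 1 fell (median 0.85, adjusted p = 7.13e-05; adjusted p = 0.145 with an estimated correlation), including Esd at 2.14 ± 0.10, and Hmox1, the haem-degrading enzyme, rose by 1.61 ± 0.46, a call lost without either LPS replicate and after correction for gene length. All 21 scavengers of reactive oxygen species rose (median 1.10, adjusted p = 1.6e-08, or 0.158 with an estimated correlation). Among them were the superoxide dismutases Sod2 at 2.86 ± 0.14 and Sod1 at 1.84 ± 0.09. Genes matched on length and expression level, a test chosen after the data were seen, had a like median of 1.09 (central range of draws 0.84 to 1.30). The heat shock and Nrf2 medians, and that of the NADPH oxidase list below, lay above their matched ranges. Of 10 genes on a list for the NADPH oxidase, which makes superoxide, 8 were higher and 1 lower (adjusted p = 0.0106, or 0.541 with an estimated correlation). The list median was 0.78. This list also held Nos2, which is not an NADPH oxidase gene and rose by 4.82 on 6 control counts.

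Short and abundant transcripts rose together in LPS. All 42 ribosomal protein genes rose, with a median log2 fold change of 1.75 (adjusted p = 1.37e-21; adjusted p = 0.145 with an estimated correlation), and so did 46 of 47 genes of oxidative phosphorylation, the mitochondrial ATP-making pathway, with a median of 1.44 (adjusted p = 4.17e-17; adjusted p = 0.306 with an estimated correlation). Of 21 antigen presentation genes 11 rose and 1 fell (median 0.39, adjusted p = 0.0349; adjusted p = 0.188 with an estimated correlation). The length trend of the LPS libraries runs through these groups. After correction for length and expression level the medians were 0.02 for ribosomal protein, 0.05 for oxidative phosphorylation, 0.22 for scavenger, 0.22 for NADPH oxidase and 0.11 for antigen presentation genes, and none of these 5 lists was called. Under the same correction, Rps9, Cox8a, Cyba and Fth1 had log2 fold changes below 0, and the rises of H2-K1, H2-D1, Psmb8, Ncf4, Sod1, Cox5b, Ndufa2 and Rps19 were not called, while the inflammatory (2.09), interferon (0.76), heat shock (0.73) and Nrf2 (0.54) lists were still called upward.

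Genes of dead-cell uptake and of lipid handling fell. Of 26 efferocytosis and scavenger receptor genes, which serve the uptake of dead cells, 13 fell and 2 rose (median -0.50, adjusted p = 0.0233; adjusted p = 0.758 with an estimated correlation), with C1qa, a complement component, at -2.77 ± 0.17 and the integrin Itgav at -2.04 ± 0.18. Of 20 lipid genes controlled by the sterol receptor LXR, 13 fell and 1 rose (median -0.67, adjusted p = 0.00713; adjusted p = 0.541 with an estimated correlation), with the cholesterol exporter Abca1 at -2.56 ± 0.27 and the desaturase Scd2 at -1.95 ± 0.18. Over the alternatives, corrections for length among them, the smallest falls were -1.08 for Itgav, -1.34 for Abca1, -1.29 for Scd2 and -2.63 for C1qa. Mrc1, the mannose receptor, fell from 258 ± 36.9 CPM (SD, n = 3) to 71.6 ± 9.83 CPM (SD, n = 2), and Arg1, arginase, had a log2 fold change of -2.56 ± 0.48. Among called genes with a mean FPKM of at least 5 and no overlap between the groups, the largest falls were those of Rnf144b and Egr3 (both -4.32), St6gal1 (-3.73), Plekhm1 (-3.72), Ocstamp (-3.66) and Plau (-3.57). Fkbp5, induced by glucocorticoids, fell by 0.94 on the log2 scale, and Tsc22d3, another such gene, had a value of -0.67 ± 0.53 that was not called.

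In total 3736 genes were higher and 3818 lower in LPS than in control, or 63.4% of those tested (edgeR's quasi-likelihood test, adjusted p of 0.05). Correction for length and expression level gave 5118 called genes. Of these, 3777 had the same call without it and 307 the opposite one. Adjusted over the list alone, the counts were the same except for inflammatory (3 fell), oxidative phosphorylation (47 rose), cell cycle (10 rose), integrated stress (6 rose, 1 fell), glucocorticoid response (6 fell) and fibroblast and endothelial marker genes (none fell). Lists for alternative activation (adjusted p = 0.634), alveolar macrophage identity (0.405), cell cycle (0.562), integrated stress (0.207), endoplasmic reticulum stress (0.634), glycolysis and hypoxia (0.799) and lysosome and autophagy (0.738) were not called. Some of these lists still differed from genes matched on length and expression level, a test chosen after the data were seen. The lysosome median was 0.06, against 0.55 in matched genes (central range of draws 0.36 to 0.75). The glycolysis and hypoxia median was -0.28, against 0.23 (-0.02 to 0.43). The medians of the other lists named here lay inside their matched ranges. On log2(FPKM + 1) with limma, 1955 genes were higher and 5574 lower, and the median of all genes was -0.42. FPKM carries no TMM scaling, and the TMM factors were 0.779 and 0.803 for LPS and 1.05 to 1.13 for the others. A shift of this sign thus follows from the scaling and does not show that most genes fell.

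**Figure D2:**
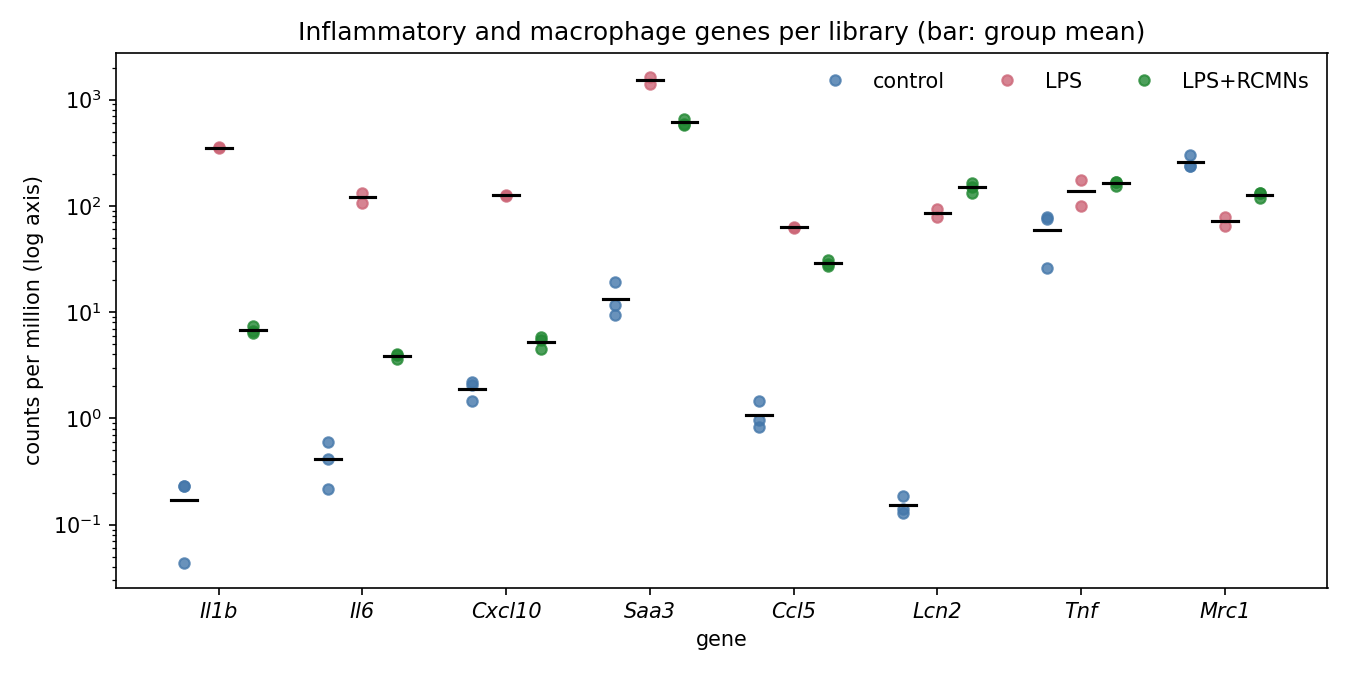
Level of 8 genes in each library in CPM on a log axis, with points for libraries, colours for groups and a bar at each group mean. Il1b, Il6 and Cxcl10 lie far lower in LPS+RCMNs than in LPS and above control, Saa3 and Ccl5 lie between the other groups, and Lcn2 lies highest in LPS+RCMNs, at 149.8 CPM against 86.1 CPM in LPS.

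The LPS+RCMNs versus LPS comparison asks what the nanoparticles changed in LPS-exposed cells, the main question of the study. Most inflammatory genes were lower with RCMNs. Il1b was at 6.82 ± 0.527 CPM (SD, n = 3) with RCMNs, a log2 fold change of -5.69 ± 0.15 against LPS alone. Il6 (-4.96 ± 0.18), the related cytokine Il1a (-4.79 ± 0.17) and Cxcl10 (-4.58 ± 0.15) fell by similar amounts. Of the 48 inflammatory genes 35 fell, 3 rose and 10 were not called (median -1.50, adjusted p = 3.23e-07; adjusted p = 0.279 with an estimated correlation). Lcn2 rose by 0.80 ± 0.12 (SE), and Tnf (0.25 ± 0.40) and Nos2 (-0.45 ± 0.42) were not called. Nos2 was called lower, at -0.79, without both libraries that stood apart, and ran to -0.86 over the alternatives. The Tnf value was -0.12 without LPS replicate 1.

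Heat shock genes and globins were lower with RCMNs than in LPS. Globins summed to 21.3 CPM with RCMNs and 13.7 CPM in control, and the heat shock list had a median log2 fold change of 0.09 against control. These differences thus rest on high levels in the 2 LPS libraries. The values do not separate an effect of RCMNs from a fault in those libraries. Hspa1a and Hspa1b were at 0.235 ± 0.326 and 0.548 ± 0.553 CPM (SD, n = 3), log2 fold changes of -11.64 ± 0.57 and -10.81 ± 0.53 on 14 and 34 counts with RCMNs. The Hspa1a value ran from -13.78 to -7.61 over the alternatives, so its size is uncertain. In all, 16 of 18 heat shock genes fell (median -1.18, adjusted p = 2.6e-06; adjusted p = 0.269 with an estimated correlation). The globin genes Hbb-bt (-7.99), Hba-a1 (-7.97), Hbb-bs (-7.90) and Hba-a2 (-7.72) followed among genes with a mean FPKM of at least 5. All 42 ribosomal protein genes (median -1.88, adjusted p = 2.77e-24; adjusted p = 0.127 with an estimated correlation) and all 47 oxidative phosphorylation genes fell (median -1.48, adjusted p = 1.35e-18; adjusted p = 0.317 with an estimated correlation). Of the scavengers of reactive oxygen species 18 of 21 fell (median -1.02, adjusted p = 1.24e-06; adjusted p = 0.279 with an estimated correlation), and 11 of 21 antigen presentation genes fell while 2 rose (adjusted p = 0.0467; adjusted p = 0.279 with an estimated correlation). The antigen presentation list was not called without LPS replicate 2 (median -0.51) or LPS+RCMNs replicate 2 (-0.50). The rank correlation of this fold change with gene length was 0.59. After correction for length and expression level the ribosomal protein (-0.26) and oxidative phosphorylation (-0.15) lists were still called, the scavenger list (-0.16) was not, and the antigen presentation median turned to 0.12 and was not called.

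Genes of dead-cell uptake and lipid handling, lower in LPS than in control, and alveolar macrophage genes, a list not called in LPS, were higher with RCMNs. Of 26 efferocytosis and scavenger receptor genes 15 rose and 4 fell (median 0.85, adjusted p = 0.00899; adjusted p = 0.6 with an estimated correlation), with the integrins Itgam at 1.67 ± 0.13 and Itgav at 2.04 ± 0.18. On log2(FPKM + 1), camera called neither this list nor the alveolar macrophage list. Among 17 alveolar macrophage genes 10 rose and 3 fell (median 1.00, adjusted p = 0.0467; adjusted p = 0.6 with an estimated correlation), including the lectin Siglec1 at 2.14 ± 0.18 and Mertk, a receptor for dying cells, at 3.69 ± 0.46 (1.37 to 3.97 over the alternatives, on 21 counts in LPS). That list was not called without LPS replicate 2 (median 0.75), without LPS+RCMNs replicate 1 (0.95) or with the replicate number as a block. Of 20 LXR lipid genes 11 rose and 2 fell (median 0.56, adjusted p = 0.0123; adjusted p = 0.6 with an estimated correlation), with Abca1 at 2.40 ± 0.27. Among called genes with a mean FPKM of at least 5 and no overlap between the groups, the largest rises were Plau, the urokinase, at 4.05 ± 0.51, Rnf144b at 3.99, Thbs1, thrombospondin-1, at 3.89, Plekhm1 at 3.66, Sirpb1c at 3.60 and Vsir at 3.27. Mrc1 rose by 0.84 ± 0.14, a call lost after correction for gene length, and Arg1 by 2.18 ± 0.47. Hmox1 (0.44 ± 0.47) was not called; its LPS+RCMNs libraries read 817.7, 219.0 and 657.9 CPM, and without LPS+RCMNs replicate 2 it was called.

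In this comparison 3555 genes were higher and 3508 lower with RCMNs, 59.3% of those tested. Adjusted over the list alone, 18 efferocytosis genes rose, and the other called lists kept their counts. Lists for Nrf2 targets (adjusted p = 0.213), interferon response (0.263), chemokine receptors and migration (0.0595), metal and iron handling (0.455) and cholesterol synthesis (0.964) were not called. Of these, migration (median 1.00, matched genes 0.07, range -0.24 to 0.32) and metal and iron genes (0.48, matched -0.07, -0.49 to 0.21) lay above matched genes. The others lay inside their ranges. The lysosome list, also not called, had a median of 0.15, against -0.45 in matched genes (-0.69 to -0.22). The glycolysis and hypoxia list, not called either, was at 0.06, against -0.15 (-0.35 to 0.05). On log2(FPKM + 1) with limma, 5202 genes were higher and 1971 lower, with a median of 0.35 over all genes, a shift of the sign that the missing TMM scaling gives.

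**Figure D3:**
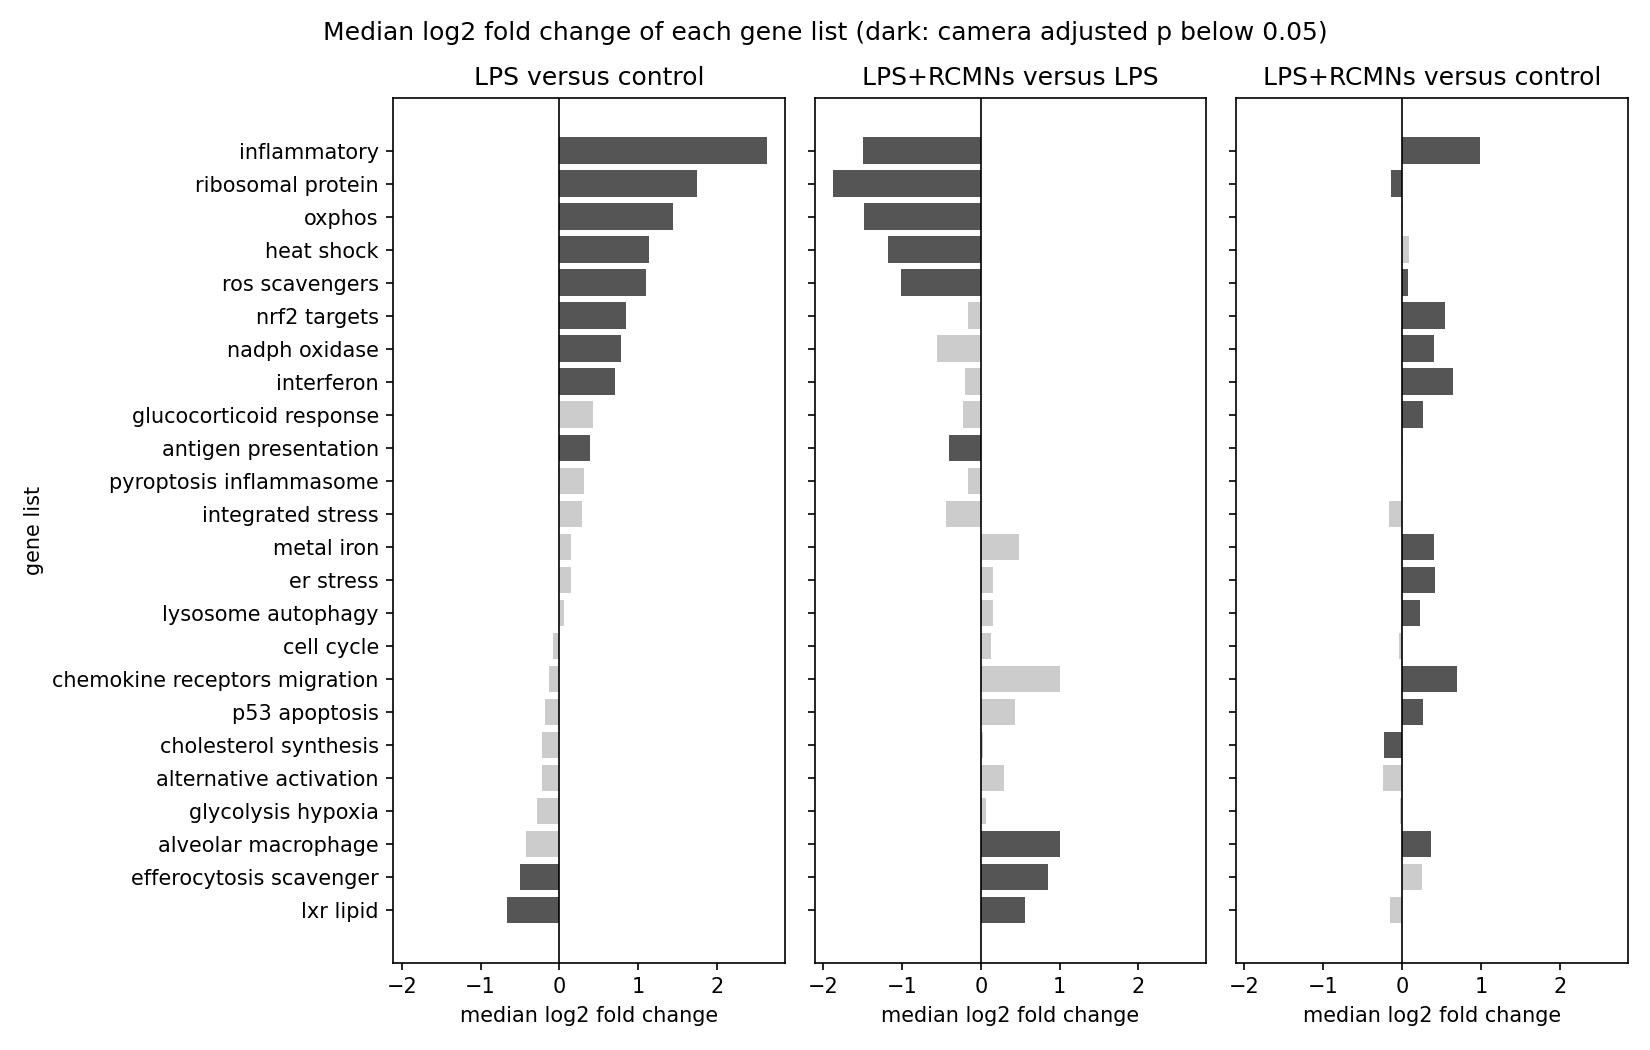
Median log2 fold change of each tested gene list other than cell type markers, with a panel per comparison and dark bars where camera called the list. The inflammatory list has medians of 2.64, -1.50 and 0.99, and the ribosomal protein list 1.75, -1.88 and -0.14.

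Most genes called in LPS versus control were also called in LPS+RCMNs versus LPS, in the opposite direction. Of the genes called in both comparisons, 6229 went opposite ways, 3140 of them higher in LPS and 3089 lower. Lists of these sizes drawn independently would share 1100 and 1140. Of the 41 inflammatory genes raised by LPS, 33 were lower again with RCMNs, 1 (Lcn2) was higher still, and 20 remained above control. Another 36 genes went the same way in both steps, 31 up and 5 down, where independent lists would share 1115 and 1124. Both comparisons contain the LPS libraries with opposite sign. Simulated groups with no change gave 0.0333 opposite and 0 same-direction calls on average over 30 draws. With no gene changed, few calls of any kind can arise, so these counts are no baseline for the real overlap. In the real comparisons 63.4% and 59.3% of genes were called, and the adjusted threshold is less strict. The fold changes correlated at -0.90 across genes, which are not independent replicates, against -0.64 in the simulation, and their covariance was -1.29 against -0.06. With 2 libraries the LPS group can be split only into single libraries, and no such split was run, so part of the excess may come from the shared libraries. A fault in the preparation of the 2 LPS libraries, which alone carry the steep length trend and the high globin levels, would also give opposite calls, and the values do not separate it from effects of LPS and RCMNs. The opposite calls numbered 3843 after correction for gene length and 3578 after correction for length and expression level. The same-direction calls numbered 12 and 9 without LPS replicates 1 and 2, and 18, 64 and 17 without LPS+RCMNs replicates 1, 2 and 3.

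The LPS+RCMNs versus control comparison asks what still differed from untreated cells when both agents were given. Some of the inflammatory genes raised in LPS were still above control. No group was given RCMNs without LPS. Differences from control thus cannot be assigned to LPS, to RCMNs or to their combination. Lcn2 was at 149.8 ± 16.1 CPM (SD, n = 3) against 0.152 ± 0.0298 CPM (SD, n = 3), a log2 fold change of 9.89 ± 0.20. The acute phase protein Saa3 (5.50 ± 0.25), Csf3 (5.53 ± 0.49), Il1b (5.30 ± 0.26), and the chemokines Ccl5 (4.73 ± 0.18) and Ccl7 (4.66 ± 0.67) also rose. Over the alternatives Csf3 ran from 2.01 to 7.30 and Il1b from 2.50 to 5.62, on the few control counts given above. Of the 48 inflammatory genes 20 rose, 2 fell and 26 were not called (median 0.99, adjusted p = 2.35e-14; adjusted p = 0.114 with an estimated correlation), and of 42 interferon genes 14 rose and none fell (median 0.64, adjusted p = 3.72e-12; adjusted p = 0.324 with an estimated correlation). Il6 rose by 3.22 ± 0.26, Nos2 by 4.37 ± 0.56 and Cxcl10 by 1.47 ± 0.17. Tnf rose by 1.46 ± 0.36 (adjusted p = 0.044), and that call was lost in 7 of the 8 fits without a library.

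Nrf2 targets were higher. Of the 28 Nrf2 targets 17 rose and none fell (median 0.54, adjusted p = 3.89e-15), and this was the list still called with an estimated correlation (adjusted p = 0.0256). Gsr, glutathione reductase, went from 104.2 ± 1.97 to 272.6 ± 12 CPM (SD, n = 3 each), a log2 fold change of 1.39 ± 0.08, and Fth1, the ferritin heavy chain, rose by 0.88 ± 0.08. Of 18 metal and iron genes 7 rose and 11 were not called (median 0.40, adjusted p = 1.81e-06; adjusted p = 0.109 with an estimated correlation), including the metal transporter Slc11a1 at 1.04 ± 0.08. Of the 10 genes on the NADPH oxidase list 4 rose and 6 were not called, with Rac2 at 0.86 ± 0.08. The list was called (adjusted p = 0.00347, or 0.344 with an estimated correlation), but not on log2(FPKM + 1). Its median was 0.41, and Nos2, not an NADPH oxidase gene, was among the members that rose, at 4.37. Of 21 scavengers 6 rose and 15 were not called (median 0.07, adjusted p = 8.93e-04; adjusted p = 0.344 with an estimated correlation), with the peroxiredoxin Prdx5 at 1.27 ± 0.09. The scavenger median ran from -0.02 to 0.14 over the alternatives, and genes matched on length and expression level had a median of 0.05. This list deviated by 0.14 in control replicate 1 and by 0.13 in LPS+RCMNs replicate 2 from the other replicates, more than its median change. Hmox1 rose by 2.05 ± 0.44 (adjusted p = 0.024), a call lost without control replicate 3, either LPS replicate, or LPS+RCMNs replicate 1 or 3. Nqo1, another Nrf2 target, was at 0.480 ± 0.263 CPM (SD, n = 3) and not called.

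Lists for migration, lysosome and alveolar macrophage identity were called upward too, and the efferocytosis and scavenger receptor list was not called (7 rose, 4 fell, 15 not called; adjusted p = 0.575). Of 23 chemokine receptor and migration genes 7 rose and 1 fell (median 0.69, adjusted p = 2.85e-06; adjusted p = 0.344 with an estimated correlation), with the matrix protease Mmp9 at 1.88 ± 0.17 and the formyl peptide receptors Fpr1 and Fpr2 at 5.31 ± 0.60 and 3.12 ± 0.30. The control levels of Fpr1 and Fpr2 rest on 15 and 35 counts, and the values ran from 2.74 to 5.84 and from 1.73 to 3.35 over the alternatives, so their size is uncertain. Of 34 lysosome and autophagy genes 7 rose (median 0.23, adjusted p = 1.31e-04; adjusted p = 0.397 with an estimated correlation), with the protease Ctsd at 1.01 ± 0.14. Of 17 alveolar macrophage genes 5 rose and 2 fell (median 0.37, adjusted p = 0.00391; adjusted p = 0.363 with an estimated correlation), with the fatty acid carrier Fabp4 at 2.35 ± 0.14. Lists for p53 targets and apoptosis (2 rose, 1 fell; adjusted p = 0.00347; adjusted p = 0.114 with an estimated correlation) and endoplasmic reticulum stress (2 rose; adjusted p = 2.42e-05; adjusted p = 0.363 with an estimated correlation) were called upward, with Ccng1 at 0.72 ± 0.08 and Sdf2l1 at 0.71 ± 0.15, a call lost without LPS+RCMNs replicate 1 or 3. In the libraries that stood apart, some lists deviated from the other replicates by more than their median change: endoplasmic reticulum stress by -0.55 in control replicate 1 (median change 0.42), and in LPS+RCMNs replicate 2 chemokine receptors and migration by -0.72, alveolar macrophage identity by -0.40, lysosome by -0.24 and cholesterol synthesis by 0.38. The pyroptosis and inflammasome list was also called upward (adjusted p = 0.0459; adjusted p = 0.397 with an estimated correlation), with a mean of 0.61 from Il1b and Il1a but a median of -0.0042. The glucocorticoid response list (2 rose, 2 fell; adjusted p = 0.0438; adjusted p = 0.344 with an estimated correlation) was led by Lcn2. Neither of these lists was called without either LPS replicate or LPS+RCMNs replicate 1 or 3, nor was the former without control replicate 2 (median 0.07) or the latter without control replicate 1 (0.11). With the replicate number as a block the pyroptosis and inflammasome list was not called. Of 5 fibroblast and endothelial markers 1, the actin Acta2, rose to 2.12 ± 0.108 CPM (SD, n = 3) (adjusted p of the list = 0.0128; adjusted p = 0.245 with an estimated correlation).

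Falls against control were fewer. Abcd2, a peroxisomal fatty acid transporter, had a log2 fold change of -1.60 ± 0.12, Selenop, the plasma selenium carrier, -1.46 ± 0.10, Ankrd37 -1.67 ± 0.26, and the complement genes C1qc and C1qa -1.46 ± 0.10 and -1.36 ± 0.14. Mrc1 was still below control at 128 ± 7.35 CPM (SD, n = 3), a value of -1.02 ± 0.12. Of 28 cholesterol synthesis genes 3 (Insig1, Lpin1 and Nsdhl) fell (median -0.23, adjusted p = 1.33e-04; adjusted p = 0.397 with an estimated correlation), and each of these 3 gene calls was lost when LPS replicate 1 or 2 or LPS+RCMNs replicate 1 or 3 was left out. None of the 42 ribosomal protein genes was called, and their median was -0.14 (adjusted p = 3.28e-06; adjusted p = 0.314 with an estimated correlation). Arg1 (-0.38 ± 0.38), Fkbp5 (0.25 ± 0.08) and Tsc22d3 (-1.12 ± 0.47) were not called. Without both libraries that stood apart, Arg1 was called lower (-0.43) and Fkbp5 higher (0.22), and Tsc22d3 was at -0.23; Arg1 read 75.1 CPM in control replicate 1 and 74.2 CPM in LPS+RCMNs replicate 2, against 142 to 212 CPM in the other control and LPS+RCMNs libraries.

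In total 516 genes were higher and 385 lower than in control, 7.56% of those tested. Adjusted over the list alone, 27 inflammatory genes rose and 5 fell, 26 interferon genes rose and 1 fell, and 22 Nrf2 targets rose. In the same way 14 chemokine receptor and migration genes rose and 2 fell, 13 lysosome genes rose and 2 fell, 7 alveolar macrophage genes rose and 3 fell, 6 p53 targets rose and 2 fell, 6 glucocorticoid response genes rose and 3 fell, 5 pyroptosis genes rose and 1 fell, 4 endoplasmic reticulum stress genes rose and 1 fell, 4 NADPH oxidase genes rose and 1 fell, and 7 scavengers and 2 fibroblast and endothelial markers rose. The metal and iron, cholesterol and ribosomal protein lists kept their counts. The count of 901 called genes was 442 and 415 without control replicates 2 and 3, 340 and 322 without LPS+RCMNs replicates 1 and 3, and 1372 without LPS+RCMNs replicate 2. With both libraries that stood apart left out, it was 3017. On log2(FPKM + 1) with limma, 399 genes were higher and 592 lower.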

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

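The alternatives chosen after seeing the data are the corrections for length, for length and GC content and for length and expression level, the fit without both libraries that stood apart, and camera on log2(FPKM + 1). Of 149 values of named genes, 114 kept direction and side of the threshold under all alternatives fixed in advance and 98 under the later ones as well. Of the 36 list calls, 1 (Nrf2 targets in LPS+RCMNs versus control) was kept under all. A minimum of a 2-fold change, which by construction removes calls, left 3619 genes for LPS versus control, 3162 for LPS+RCMNs versus LPS, 314 for LPS+RCMNs versus control, 2644 opposite and 10 same-direction calls. Correction for length and expression level gave 4618 genes for LPS+RCMNs versus LPS, of which 3426 had the same call without it and 207 the opposite one, and 3578 opposite calls; correction for length gave 3843, or 3874 with GC content. The count for LPS+RCMNs versus control was 1379 with DESeq2, 3017 without both libraries that stood apart and 322 to 1372 without a library; the same-direction count was 22 with the stricter filter, 135 without both libraries and 9 to 64 without a library. Whether replicate numbers pair the samples cannot be decided from the deviations, and not every sample correlated best with its own number. Same-numbered deviations correlated at -0.28, -0.34 and 0.20 between control and LPS+RCMNs. They correlated at 0.19 and 0.14 between control and LPS, and at -0.11 and -0.14 between LPS and LPS+RCMNs. The libraries that stood apart, control replicate 1 and LPS+RCMNs replicate 2, carry different numbers and shape these values. They correlated at 0.38 with each other. LPS replicate 1 correlated at 0.19 with the former and 0.14 with the latter. The deviations of LPS replicates 1 and 2 mirror each other by construction. A grouping of these libraries across the 3 groups was not used as a block in any fit. The replicate block gave 454 genes for LPS+RCMNs versus control and 15 same-direction calls. With an estimated correlation 0, 0 and 1 lists were called, against 11, 9 and 16.

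Under correction for length and expression level these values reversed: Cyba (-0.19), Fth1 (-0.12), Cox8a (-0.0897) and Rps9 (-0.0088) for LPS versus control, Cox8a (0.019) and Rps18 (0.040) and the antigen presentation list (0.12) for LPS+RCMNs versus LPS. Tsc22d3 for LPS versus control reversed to 0.31 without both libraries that stood apart, with a range of -0.96 to 0.31 without a library, and for LPS+RCMNs versus LPS to 0.015 with limma. Tnf for LPS+RCMNs versus LPS ranged from -0.12 to 0.68 without a library, and was 0.88 after correction for length and expression level. Where the alternative's construction does not show it, the cause was not tested. Leaving out an LPS replicate leaves 1 library, which is assumed to vary like the other groups. Changes of 1.5-fold were recovered in 29.9% of the 67 genes so changed in the simulation of LPS versus control. Few of the 11911 simulated genes were changed, whereas 63.4% were called in the real comparison, where the adjusted threshold is less strict. There Msn was called at a log2 fold change of 0.26. The simulated share thus does not give the sensitivity of the real comparison, in which small changes may still have been missed. The alternatives with pseudocounts of 0.1 and 5 did not apply, because counts were deposited.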

Other observations

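All tests in this part were chosen after the results were seen, except the splits of the samples, which were fixed before. Genes called in LPS+RCMNs against both other groups were looked for after the values were seen: 192 were higher than both and 69 lower than both. After correction for gene length 141 and 43 of them had the same calls, and 136 and 42 after correction for length and expression level. No list was tested on these sets, and the genes given here were picked after they were seen. The higher set held the integrin Itgam at 1257 ± 139 CPM (SD, n = 3) against 784.1 ± 63.8 in control (SD, n = 3) and 394.3 ± 43.5 in LPS (SD, n = 2), the antibody receptor Fcgr1 at 168.4 ± 27.9 against 65.0 ± 14.4 and 56.2 ± 5.93, the complement protein C3 at 83.6 ± 18.1 against 27.1 ± 4.52 and 23 ± 1.06, and the lysosomal protease Ctsd at 2746 ± 478 against 1359 ± 130 and 1407 ± 219. Adgre1, the macrophage marker F4/80, was at 583.9 ± 40.6 CPM against 296.7 ± 8.47 and 409.1 ± 66.6.

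Among the genes lower than both, Tlr2, a receptor for bacterial lipoproteins, was at 53.4 ± 6.24 CPM (SD, n = 3) against 92.6 ± 1.48 in control (SD, n = 3) and 157.6 ± 0.929 in LPS (SD, n = 2). Relb, a subunit of NF-kappaB, was at 5.34 ± 1.72 against 10.5 ± 0.374 and 24.8 ± 5.09, and the chemokine Pf4 at 50.9 ± 1.57 against 83.0 ± 4.89 and 214.1 ± 4.66. The complement genes C1qb and C1qc were also in this set, but lost a call after correction for length.

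Ribosomal protein and oxidative phosphorylation genes were higher in both LPS libraries than in control, with medians of 1.75 and 1.44 (SD over members 0.192 and 0.433). GC content is argued against, since its removal left medians of 1.72 and 1.49, while removal of a trend on length alone took most of the rise, leaving 0.46 and 0.29 (SD 0.424 and 0.402), though both lists were still called (adjusted p 6.74e-10 and 8.06e-04), so length alone is not the whole source. Genes outside all lists, matched on length and expression level, had medians of 1.64 (95% of draws 1.53 to 1.70) and 1.36 (1.18 to 1.45). The oxidative phosphorylation median lay just inside its range, with a share of 0.027 of the draws as high. In LPS+RCMNs versus LPS its median of -1.48 lay outside the matched range (-1.41 to -1.08). A length trend that is steeper for abundant genes may thus account for most of the oxidative phosphorylation value, by a narrow margin for all of it. For the ribosomal proteins such a trend cannot be told apart from a further small rise: their median lies above the draws, yet a surface on length and level, which these genes help to shape, takes that median to 0.02 (SD 0.417) and ends the call. The trend itself is confounded with the LPS group, so an effect of LPS stays open and untested, though the LPS+RCMNs cells received LPS and show no trend of that size.

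Globin transcripts stood at 4959 ± 892 CPM (SD, n = 2) in the LPS libraries. A length trend is argued against, since the 4 globin genes kept a median log2 fold change of 7.17 after correction for length and expression level. RNA of red blood cells or their precursors may be present and cannot be told from other sources: 8 of 17 other erythroid genes had both LPS libraries above the other 6, against 4.93 on average in 10000 random lists (permutation p = 0.0801, adjusted over the 5 sets tested 0.134), with Alas2 at 31.6 ± 2.32 CPM but Slc4a1 at 0.212 ± 0.0428 CPM (SD, n = 2). White blood cell RNA is as open: 8 of 16 lymphocyte and 5 of 11 neutrophil markers did so, against 4.09 and 2.20 (adjusted 0.1085 for both), while S100a8 and S100a9, among the most abundant transcripts of neutrophils, stood at 2.18 and 2.42 CPM; pooling these 2 lists, a choice made after both results were known, gave a permutation p of 0.0030. Of the 5 sets, epithelial (1 of 12; adjusted 0.866) and fibroblast and endothelial markers (3 of 11; 0.572) showed no excess, and no biological explanation was tested.

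Control replicate 1 and LPS+RCMNs replicate 2 stood apart from their groups. Their deviations from the other replicates correlated at 0.382 across genes, the highest of the 9 pairs of a control with an LPS+RCMNs library, so a shared difference that the labels do not record is a candidate explanation, from the values in which it was noticed. A swap of their labels is argued against by Lcn2, Saa3 and Ccl5, for which all 6 levels lay closer to the library's own group, and a length trend by a correlation of 0.379 after its removal. They also share low globin levels, 0.477 and 0.608 CPM against 20.1 to 33.5 CPM in the other control and LPS+RCMNs libraries, but differ in others: the integrated stress list had a median deviation of 0.81 in control replicate 1, with the kinase-like gene Trib3 at 73.5 CPM against 7.59 and 6.55, and 0.23 in LPS+RCMNs replicate 2, and no biological explanation was tested.

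Of the 10 splits of the 6 control and LPS+RCMNs libraries, 1, the real one, gave 901 called genes, and the highest of the others gave 0 by edgeR (up to 1463 genes at an unadjusted p under 0.05, against 2727 in the real split). The splits are too few for a share under 0.05.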
